A study of Mus musculus with 12 samples.

How the data were processed

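Mouse E14 embryonic stem cells carrying a fusion of a Cas protein with Alkbh5, the enzyme that removes the m6A mark from RNA, were grown on gelatin with serum and LIF. They received a plasmid coding for a guide RNA, were selected with 8 µg/mL blasticidin for 3 days and were then held for 5 days in 200 nM INK128, an inhibitor of the growth kinase mTOR that brings embryonic stem cells into a paused, slowly dividing state. RNA came from 200000 cells per sample, per the labels' protocols, and synthetic ERCC RNAs were added to it in a fixed amount before polyA selection and directional library preparation. The 12 libraries form 3 groups of 4: a non-targeting guide (NT), Mycn-gRNA2 and Mycn-gRNA3. Groups and replicate numbers were taken from the sample titles, and the labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

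The deposited count table holds raw reads per gene for 24421 genes and 92 ERCC RNAs. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.0 and counted with featureCounts of Subread 1.5.0 on genome build mm10, and edgeR 3.32.1 was used. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping antisense genes, among them the antisense transcript at Mycn, cannot be separated from the gene's own. A second deposited table gives log2 values for 12042 genes. Tested against the counts, each value equals log2(count + 0.5) minus a constant per library, exact to 1e-13, and the constants lie within 0.0015 of those from TMM factors over the ERCC RNAs and within 0.048 of those from ERCC totals. These deposited log2 values were therefore read as levels per ERCC RNA and used only in an alternative test.

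Library sizes ran from 17248564 to 33819855 endogenous reads, with 1.03% to 1.6% of reads on ERCC RNAs. The ERCC profiles of all library pairs had a Pearson correlation of at least 0.997 across the 45 ERCC RNAs with a mean of 20 reads or more. Counts of the 18 pairs of replicates within groups differed by more than sampling noise, with chi-square per degree of freedom from 8.57 to 72.8, so no library was taken for a copy of another. Intervals on read ratios cover counting error only, since the reads carry no molecular identifiers.

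Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, robust, all 12 libraries in a fit with a term per group, genes kept by filterByExpr, 14497 genes). Calls needed a Benjamini-Hochberg adjusted p under 0.05. Levels were scaled in 2 ways. TMM factors over endogenous genes give levels relative to the transcriptome, and library sizes set to the ERCC totals give levels per ERCC read, called levels per cell because equal cell numbers were extracted. The ERCC RNAs were added to extracted RNA, so differences between samples in cell counting or RNA yield would enter these levels. Such differences were not checked. CPM values are TMM-scaled. The comparisons were both Mycn guides against NT, each guide against NT and Mycn-gRNA3 against Mycn-gRNA2. Endogenous reads per ERCC read were compared on the log2 scale by exact two-sided permutation tests.

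Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists with tested members, and again with an estimated correlation. The lists were MYC family and partners, MYC target genes, ribosome biogenesis, cytosolic ribosomal proteins, translation factors, RNA polymerase II and elongation, m6A machinery, naive pluripotency, general pluripotency, formative and primed epiblast, primitive endoderm, mesendoderm, neuroectoderm, trophoblast, 2-cell-like, fibroblast or feeder, G1/S phase, G2/M phase, p53 targets and CDK inhibitors, integrated stress response, cholesterol synthesis, lysosome and autophagy, oxidative phosphorylation, glycolysis and hypoxia, interferon response, MAPK and immediate early, imprinted genes, replication-dependent histones and mitochondrially encoded. The lists, the tests, the alternatives (except those chosen after seeing the data) and the rule for named genes were fixed before the data were examined. The rule takes Mycn, Myc and Alkbh5, the 10 largest rises and 10 largest falls with both guides among called genes with a mean log2 CPM of at least 1 and all guide libraries on the same side of the NT mean, the 5 largest each way per guide, and up to 4 called members with the lowest adjusted p from each list. Further list members named to complete a small count were chosen after their values were seen. Some members of the lists are not reported here by name.

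The procedures were tested on simulated counts drawn from the means and library sizes of these samples for 14392 genes. For both guides against NT, edgeR recovered 65.7% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold, with 10 of 14192 unchanged genes called. A simulated global rise of 0.38 on the log2 scale came out at a median of 0.37. Changes were placed only in genes above a minimum expected read count. Libraries were drawn independently, without deviations shared between replicates, and ERCC reads varied by sampling alone. The rates hold for that setting and leave out such further variation.

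Alternatives tried were DESeq2 1.42.0, other size factors, no filter on low counts, a fit of the compared groups alone, a 1.5-fold minimum, the replicate number as a block, each library left out in turn, limma on the deposited log2 values, other ERCC and endogenous totals, fry in place of camera, and settings chosen after seeing the data. Same-numbered Mycn-gRNA2 and Mycn-gRNA3 libraries deviated together from their group means, with correlations across genes of 0.37, 0.26, 0.5 and 0.21 for replicates 1 to 4. Mycn-gRNA2 replicates 1, 2 and 3 correlated best with their own number, and replicate 4 did not. The pairing of these guides thus comes from the titles' numbers, and this check bears it out in part. A difference of replicates 1 and 2 from 3 and 4 in each group could also give such correlations.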

Results

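PolyA RNA was sequenced from 12 libraries of paused mouse embryonic stem cells, 4 with a non-targeting guide (NT), 4 with Mycn-gRNA2 and 4 with Mycn-gRNA3. The design asks whether steering an m6A demethylase to the transcript of Mycn, a MYC-family transcription factor that drives growth, changes its level and the RNA output of paused cells. The NT libraries held 22776016, 21822509, 25069479 and 23003958 endogenous reads in replicates 1 to 4. The Mycn-gRNA2 libraries held 23583573, 17248564, 23778808 and 26405190, and the Mycn-gRNA3 libraries 24240057, 26548892, 27470845 and 33819855.

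Mycn, at chromosome 12, positions 12936093 to 12941836 of mm10, was higher in all 8 libraries with a Mycn guide than in any NT library. Its level was 141 ± 4.17 CPM in NT (SD, n = 4), 236 ± 26.7 CPM with Mycn-gRNA2 (SD, n = 4) and 276 ± 16.7 CPM with Mycn-gRNA3 (SD, n = 4). Relative to the transcriptome, Mycn rose by 0.86 on the log2 scale with both guides (SE 0.0699, edgeR adjusted p = 3.39e-06), by 0.75 with Mycn-gRNA2 (adjusted p = 3.76e-05) and by 0.97 with Mycn-gRNA3 (adjusted p = 4.13e-06). Per 1000 ERCC reads it stood at 9.23 ± 1.08 in NT, 19.3 ± 4.74 with Mycn-gRNA2 and 25.3 ± 2.95 with Mycn-gRNA3 (SD, n = 4 each), a rise per cell of 1.26 with both guides (edgeR adjusted p = 9.32e-09). Myc, the paralog that also drives growth, had a relative log2 fold change of 0.07 (SE 0.12, edgeR adjusted p = 0.709), and Alkbh5 one of −0.004 (SE 0.0567, edgeR adjusted p = 0.967). Per cell, where the median over all genes moved by 0.39, Myc rose by 0.46 (edgeR adjusted p = 0.008) and Alkbh5 by 0.39 (edgeR adjusted p = 0.0107). Reads of the Alkbh5 fusion and of the endogenous gene were not separated, and the strand setting behind the Mycn counts is not given in the sources used here. With replicates 1 and 2 alone, a setting chosen after seeing the data, the Mycn-gRNA2 change was 0.58 (edgeR adjusted p = 0.0918).

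Endogenous reads per ERCC read measure polyA RNA per cell if cell counts and RNA yield were equal between samples, which was not checked. They were 65.5 ± 4.66 in NT (SD, n = 4), 81.9 ± 12.4 with Mycn-gRNA2 (SD, n = 4) and 90.2 ± 5.13 with Mycn-gRNA3 (SD, n = 4). Both guides together stood 1.31-fold above NT (log2 difference 0.39, SE 0.0803, exact permutation p = 0.00404, adjusted over 3 comparisons 0.0121), with 7 of 8 guide libraries above every NT library. This permutation treats the libraries as independent, though same-numbered guide libraries deviated together. An exact sign-flip test with the replicate number as a block did not pass, but 4 pairs cannot give a p under 0.05. Mycn-gRNA3 differed from NT by 0.46 (exact permutation p = 0.0286, the smallest that 4 against 4 allow, adjusted 0.0429). Mycn-gRNA2 differed by 0.31, which did not pass (exact permutation p = 0.0571). Of its 4 libraries 3 stood above every NT library, and replicate 2, at 65.6, did not. Without replicate 2 the difference was 0.42 (exact permutation p = 0.0286, the smallest that the remaining libraries allow). Leaving out the library that overlaps NT fixes that p, so it adds no support. Without replicate 4 the difference was 0.23. The guides did not differ detectably from each other (0.15, SE 0.121, exact permutation p = 0.314). Within replicates 1 and 2 alone the difference for both guides was 0.32 (exact permutation p = 0.267) and within 3 and 4 alone 0.46 (exact permutation p = 0.0667), where 2 or 4 libraries against 2 leave little room for a low p.

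**Figure D1:**
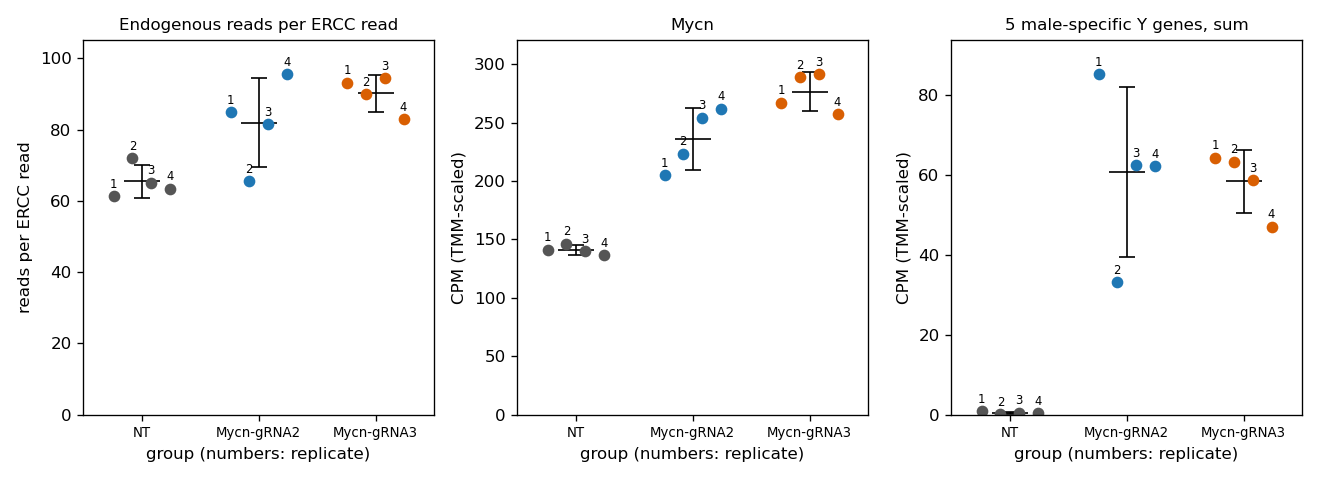
Each point is a library, numbered by replicate, with bars for the group mean and SD (n = 4), showing endogenous reads per ERCC read, Mycn in TMM-scaled CPM and the summed CPM of 5 male-specific Y genes by group. Mycn lies between 136 and 146 CPM in NT and between 205 and 292 CPM in the guide libraries, and the Y genes sum to at most 0.857 CPM in NT and at least 33.1 CPM with a Mycn guide.

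With both Mycn guides against NT, 29 of 66 MYC target genes, 12 of 20 primitive endoderm genes and 8 of 15 fibroblast genes rose and 12 of 20 naive pluripotency genes fell relative to the transcriptome. Transcripts of the Y chromosome were near 0 in all 4 NT libraries and present in all 8 guide libraries, and genes of chromosomes 1 and 8 had lower medians with the guides. With a single control guide, a difference between the NT and guide cultures and an effect of the guides are not separated in any comparison with NT. The 4 lists were called by camera with a preset correlation, and none with an estimated correlation (adjusted p = 0.686, 0.218, 0.254 and 0.546 in that order). Nop16, a nucleolar protein, rose by 0.81 on the log2 scale (SE 0.0905, edgeR adjusted p = 3.37e-05). Col4a1, a basement membrane collagen, rose by 1.43 (SE 0.142, edgeR adjusted p = 1.38e-05), and Nanog, a core factor of naive pluripotency, fell by 0.61 (SE 0.0656, edgeR adjusted p = 2.78e-05) from 489 ± 23.2 CPM in NT (SD, n = 4), with −0.22 per cell (edgeR adjusted p = 0.124). Among 14497 genes tested, 2156 rose and 1878 fell relative to the transcriptome. Of these, 546 rose and 46 fell by 2-fold or more.

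The largest rises included 4 Y-linked genes. Kdm5d, a histone demethylase, had 1 read in the 4 NT libraries together and 10.2 ± 2.9 CPM in the 8 guide libraries, a ratio of 941 with a counting interval of 169 to 37200. Eif2s3y, a translation initiation factor, had 3 NT reads and a ratio of 586 (interval 200 to 2840), and Ddx3y, an RNA helicase, had 3 NT reads and a ratio of 536 (interval 183 to 2600). Uty, a histone demethylase paralog, had 4 NT reads and 12.3 ± 3.12 CPM with the guides, a ratio of 285 (interval 111 to 1050). Olig2 and Olig1, transcription factors of the oligodendrocyte and motor neuron lineages, rose from 0.0517 ± 0.061 and 0.29 ± 0.0579 CPM in NT (SD, n = 4), with read ratios of 214 (interval 91.7 to 660) and 46.4 (interval 31.8 to 70.6). Acta2, smooth muscle actin, had 4 NT reads and a ratio of 87.4 (interval 34 to 321). Cd109, a surface protein that binds TGF-beta, had 33 NT reads and a ratio of 26.8 (interval 19 to 39.1). Myl3, a myosin light chain of heart and slow muscle, had 16 NT reads and a ratio of 23.4 (interval 14.3 to 41.2), and Pof1b 116 NT reads and a ratio of 13.8 (interval 11.5 to 16.8).

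The largest falls were smaller. Klhdc7a fell by 1.44 on the log2 scale (SE 0.22, edgeR adjusted p = 0.000381) and Dock10 by 1.32 (SE 0.186, edgeR adjusted p = 0.000195). Nsg2, a neuronal vesicle protein, fell by 1.24, Crtac1, a cartilage matrix protein, by 1.24, Panct2 by 1.21 and En1, a homeobox factor of the midbrain, by 1.20. Rcan2, a calcineurin regulator, fell by 1.16, Sult5a1, a sulfotransferase, by 1.14, Rian, a maternally expressed imprinted RNA, by 1.08 and Srgap3 by 1.03. All 10 also fell per cell, from −0.65 for Srgap3 to −1.07 for Klhdc7a. Dock10, Panct2 and En1 lie on chromosome 1 and Sult5a1 on chromosome 8. Median log2 fold changes by chromosome were taken over genes with a mean log2 CPM above 3, which leaves out Panct2, En1 and Sult5a1. These medians were −0.13 and −0.12 for chromosomes 1 and 8, against −0.07 to 0.03 on the other autosomes.

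Of 66 tested MYC target genes, 29 rose and 1, Tfb2m, fell (29 and 1 adjusted over the list alone), and 36 did not pass (camera adjusted p = 9.31e-06, adjusted p = 0.686 with an estimated correlation). Srm, which makes spermidine, rose by 0.83, Odc1, the rate-limiting enzyme of polyamine synthesis, by 0.59, and Polr1b, a subunit of RNA polymerase I, by 0.38. In Mycn-gRNA2 replicate 2, whose Y genes summed to 33.1 CPM, the 18 MYC targets called higher with Mycn-gRNA2 without that library stood at a median of 1.08 of the distance from NT to the other Mycn-gRNA2 libraries. The same measure ran from 0.499 to 1.5 over the other guide libraries. Of 13 MYC family members and partners, Mycn and Mxi1, a MAX partner that opposes MYC, rose, and Mnt, another such partner, fell relative to the transcriptome by 0.23 but not per cell (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.623). The Mnt call ended without any of 8 libraries, namely NT replicates 1, 2 and 4, Mycn-gRNA2 replicates 2 and 3 and Mycn-gRNA3 replicates 2, 3 and 4 (edgeR adjusted p from 0.0536 to 0.128), and the Mxi1 call without NT replicate 3 (0.0905) or 4 (0.0678). Ribosome biogenesis genes hardly moved as a group relative to the transcriptome: of 58, Gar1, Polr1e and Nop10 rose and Nop58 and Rpf1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.623). Of 78 cytosolic ribosomal protein genes, 4 rose, Rps12 by 0.27, Rpl36 by 0.28, Rpl41 by 0.49 and Rpl18 by 0.44 (1 and 0 adjusted over the list alone, camera adjusted p = 0.139). Without NT replicate 3 the calls of Polr1e (edgeR adjusted p = 0.0919), Rpl18 (0.0568) and Rpl41 (0.064) ended, and without NT replicate 4 those of Polr1e (0.083), Rpl18 (0.0662), Rpf1 (0.0766) and Rpl36 (0.0556). Of 41 translation factors, 8 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.101), with Eif4e, the cap-binding protein, up by 0.34. Of 51 genes of RNA polymerase II and elongation, 7 rose and 8 fell relative to the transcriptome (7 and 8 adjusted over the list alone, camera adjusted p = 0.863). Polr2a, the large subunit, fell by 0.32 on that scale, with 0.08 per cell (edgeR adjusted p = 0.59), and Polr2l, a small subunit, rose by 0.56. Of 20 genes of the m6A machinery, Rbm15, an adaptor of the methyltransferase complex, rose by 0.62 and Ythdf2, a reader that promotes decay, by 0.38 (2 and 0 adjusted over the list alone, camera adjusted p = 0.608).

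Of 20 naive pluripotency genes, 12 fell and 1 rose relative to the transcriptome (13 and 1 adjusted over the list alone, camera adjusted p = 6.21e-05, adjusted p = 0.546 with an estimated correlation), whereas per cell 2 fell and 4 rose. Prdm14, a repressor of differentiation, fell by 0.82 and by 0.43 per cell, and Tet2, which oxidises methylated cytosine, fell by 0.64, with −0.25 per cell (edgeR adjusted p = 0.0697). Dppa3, a factor of germ cells and naive cells, was the member that rose, by 1.59. Of 19 general pluripotency genes, Lin28b and Zscan10 rose and 5 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.0961), among them Zfp281, Sall1, Gdf3 and Mybl2, and 0 of the 5 fell per cell. The Zscan10 call ended without NT replicate 1, 2 or 3 or Mycn-gRNA3 replicate 3 (edgeR adjusted p from 0.0539 to 0.092). Of 18 formative and primed epiblast genes, 9 rose and 1, Zic2, fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0493, adjusted p = 0.686 with an estimated correlation). Pou3f1, a factor of the postimplantation epiblast, rose by 1.20, Lef1, a Wnt effector, by 2.17, and Sox3 by 2.01, and Cdh2, N-cadherin, rose too. The call of this list ended without any of 10 of the 12 libraries in turn, all but NT replicate 2 and Mycn-gRNA3 replicate 1 (camera adjusted p from 0.0517 to 0.0957).

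Markers of other lineages went both ways in the same libraries. Of 20 primitive endoderm genes, 12 rose and 1, Sox7, fell (12 and 2 adjusted over the list alone, camera adjusted p = 9.31e-06, adjusted p = 0.218 with an estimated correlation). Lrp2, an endocytic receptor, rose by 0.99 from 72.9 ± 11.2 CPM, Col4a2 by 1.34, and Foxa2, an endoderm factor, from 6 reads in the 4 NT libraries (ratio 35.4, interval 16.2 to 97.1). Of 15 fibroblast or feeder genes, 8 rose and 1, Fbn1, fell relative to the transcriptome but not per cell (8 and 1 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.254 with an estimated correlation). Col5a2, a fibrillar collagen, rose by 1.88 to 1.72 ± 0.295 CPM with Mycn-gRNA2 and 2.21 ± 0.292 CPM with Mycn-gRNA3 (SD, n = 4 each), so it stayed at a low level. Of 14 mesendoderm genes, Kdr, a VEGF receptor, rose by 2.97, Snai1 by 1.52 and Wnt3 by 1.65, and Fgf17 and Evx1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.238). Of 12 neuroectoderm genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.863): Pax6, Tubb3 and Neurod1 rose with Olig2, and Sox1, a neural plate factor, fell by 0.77, with Ncam1, Sox11 and Stmn2.

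Some metabolic and stress genes rose relative to the transcriptome, where over all genes 2156 of 14497 rose and 1878 fell. The share that rose was near that of all genes for cholesterol synthesis and below it for oxidative phosphorylation. Of 28 glycolysis and hypoxia genes, 10 rose and 1, Slc2a3, fell relative to the transcriptome (11 and 1 adjusted over the list alone, camera adjusted p = 0.00262, adjusted p = 0.686 with an estimated correlation). Bnip3, a mitophagy receptor induced by hypoxia, rose by 1.06, Hk1, hexokinase, by 0.36, and Aldoc, aldolase C, by 0.86. Of 32 integrated stress response genes, 8 rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.754 with an estimated correlation), among them Stc2, a secreted glycoprotein, by 1.27 and Psat1, an enzyme of serine synthesis, by 0.97. Of 26 cholesterol synthesis genes, 4 rose and 0 fell, among them Dhcr7 by 0.56, Cyp51 by 0.30 and Sqle by 0.34 (4 and 0 adjusted over the list alone, camera adjusted p = 0.012, adjusted p = 0.725 with an estimated correlation). Of 52 oxidative phosphorylation genes, Cox6c, Uqcrh, Cox8a and Cox7c rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.0961). The Cox8a call ended without NT replicate 1 or 3 or replicate 3 of either guide (edgeR adjusted p from 0.05 to 0.1). The Cox7c call ended without NT replicates 1, 3 or 4, Mycn-gRNA2 replicate 2 or Mycn-gRNA3 replicates 2, 3 or 4 (edgeR adjusted p from 0.0554 to 0.129), and the Sqle call without NT replicates 3 or 4, Mycn-gRNA2 replicate 3 or Mycn-gRNA3 replicates 2 or 3 (0.0516 to 0.0998). Of 23 MAPK and immediate early genes, Fos, Dusp1, Egr1, Ccnd1 and Ier2 fell relative to the transcriptome (0 and 5 adjusted over the list alone, camera adjusted p = 0.0493, adjusted p = 0.686 with an estimated correlation), with Fos, an AP-1 subunit, down by 0.77, whereas per cell 9 of the 23 rose and 0 fell. Of 43 G1/S genes 5 rose and 5 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.789), with Ccne1, cyclin E1, up by 0.59. Of 53 G2/M genes 5 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.863), with Aurka, a mitotic kinase, up by 0.89. The cholesterol call ended without NT replicate 3 (camera adjusted p = 0.0557), NT replicate 4 (0.0857) or Mycn-gRNA2 replicate 2 (0.059), and the MAPK call without any of 8 libraries, namely NT replicates 1, 3 and 4, Mycn-gRNA2 replicates 1, 2 and 3 and Mycn-gRNA3 replicates 1 and 2 (camera adjusted p from 0.0542 to 0.168).

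**Figure D2:**
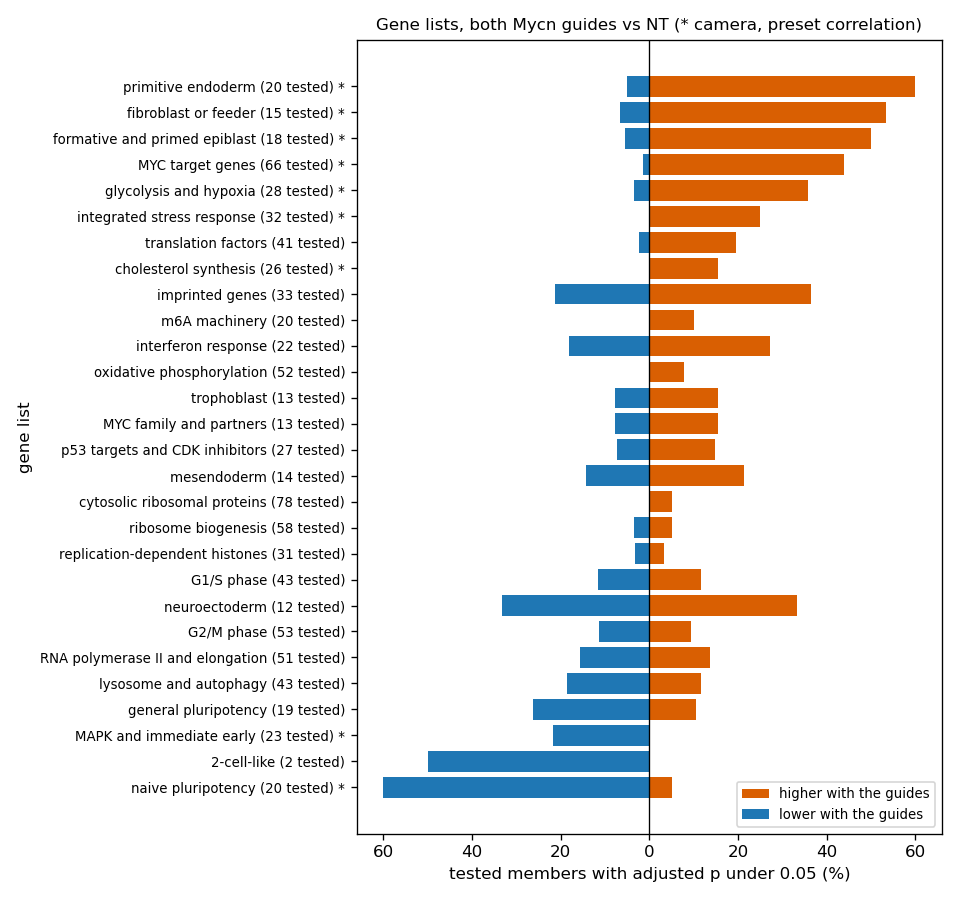
Bars give, for each gene list, the percentage of tested members higher (right) or lower (left) with both Mycn guides than in NT at an edgeR adjusted p under 0.05, relative to the transcriptome, and a star marks lists called by camera with the preset correlation. Of 28 lists 9 are called, 7 higher and 2 lower, and 0 with an estimated correlation.

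Per cell, most of these genes stood higher with both guides, since the median over all genes moved by 0.39 on the log2 scale. On that scale 8177 genes rose and 135 fell, so 98.4% of calls were rises, against 53.4% relative to the transcriptome. Tfb2m, Zic2, Sox7, Slc2a3, Fgf17, Sox11, Stmn2, Nop58 and Rpf1, lower relative to the transcriptome, did not pass per cell. Of the MYC targets 60 of 66 rose per cell, of the ribosomal protein genes 69 of 78 and of the ribosome biogenesis genes 54 of 58, each with 0 that fell. Over all 14497 genes 57.3% were called per cell, nearly all higher. The median per-cell changes of these lists were 0.599, 0.475 and 0.41 in that order, against 0.39 over all genes. Their counts therefore include the shift of all genes. For the relative counts, replicates 1 and 2 alone called 178 genes and replicates 3 and 4 alone 6385, settings chosen after seeing the data, and leaving out Mycn-gRNA2 replicate 1 gave 6157. At a 1.5-fold minimum 1471 genes were called relative to the transcriptome and 3570 per cell, and replicates 1 and 2 alone called 1113 per cell.

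With Mycn-gRNA2 alone against NT, 1462 genes rose and 1023 fell relative to the transcriptome, with the same limit on the control. The 5 largest rises were again Kdm5d, Eif2s3y, Ddx3y, Uty and Olig2, and the largest falls were Klhdc7a (−1.37), Nsg2 (−1.27), Dock10 (−1.21), Msln, a mesothelial surface protein (−1.19), and Crtac1 (−1.19). Of the MYC targets 21 rose and 0 fell (24 and 1 adjusted over the list alone, camera adjusted p = 3.26e-05, adjusted p = 0.63 with an estimated correlation), and of the naive pluripotency genes 1 rose and 11 fell (1 and 13 adjusted over the list alone, camera adjusted p = 3.26e-05, adjusted p = 0.415 with an estimated correlation). Of the primitive endoderm genes 11 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 2.93e-06, adjusted p = 0.15 with an estimated correlation). In all 9 lists were called, and 5 without Mycn-gRNA2 replicate 2. With an estimated correlation 0 of 28 were called (lowest adjusted p = 0.15, and 0.221 for the fibroblast genes). The calls for cholesterol synthesis, glycolysis and hypoxia, the integrated stress response, replication-dependent histones and MAPK genes each ended without at least 1 library, whereas those for MYC targets, naive pluripotency, primitive endoderm and fibroblast genes held without each library. Per cell 3817 genes rose and 75 fell, with a median of 0.31. The difference in endogenous reads per ERCC read, on which these counts rest, did not pass for this guide (exact permutation p = 0.0571). The relative count of 2485 became 1619 without Mycn-gRNA2 replicate 3, 4114 without its replicate 1, 1549 with only these groups in the fit and 33 with replicates 1 and 2 alone. The per-cell count of 3892 became 1866, 2463 and 2279 without NT replicates 1, 3 and 4, and 7946, 2530 and 1965 without Mycn-gRNA2 replicates 2, 3 and 4.

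With Mycn-gRNA3 alone against NT, 2147 genes rose and 1772 fell relative to the transcriptome, again with that limit. The same 5 genes led the rises, and Klhdc7a (−1.50), Dock10 (−1.44), Panct2 (−1.35), En1 (−1.30) and Crtac1 (−1.28) the falls. Of the MYC targets 25 rose and 1 fell (32 and 1 adjusted over the list alone, camera adjusted p = 1.61e-05, adjusted p = 0.718 with an estimated correlation), and of the naive pluripotency genes 2 rose and 11 fell (2 and 13 adjusted over the list alone, camera adjusted p = 0.000193, adjusted p = 0.665 with an estimated correlation). Of the ribosomal protein genes 8 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00647, adjusted p = 0.718 with an estimated correlation), and of the oxidative phosphorylation genes 10 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.00877, adjusted p = 0.718 with an estimated correlation). Without NT replicate 4 the oxidative phosphorylation call ended (camera adjusted p = 0.0725). With Mycn-gRNA2 neither list was called with all libraries, but without its replicate 1 the oxidative phosphorylation genes were (camera adjusted p = 0.0202, against 0.659 with all). The difference between the guides was not tested for lists. Per cell 8794 genes rose and 73 fell, with a median of 0.48. The relative count of 3919 became 6012 without Mycn-gRNA2 replicate 1, 6040 with only these groups in the fit and 226 with replicates 1 and 2 alone.

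Between Mycn-gRNA3 and Mycn-gRNA2, 0 genes passed relative to the transcriptome in edgeR (1273 at an unadjusted p under 0.05), and DESeq2 called 1, Rhox5, an X-linked homeobox gene. Per cell edgeR also called 1 gene (1601 at an unadjusted p under 0.05), again Rhox5, named here after its value was seen. It stood at 1.42 ± 0.323 reads per 1000 ERCC reads with Mycn-gRNA2 and 2.9 ± 0.42 with Mycn-gRNA3 (SD, n = 4 each), a log2 difference of 1.02 (SE 0.175, edgeR adjusted p = 0.0114). Mycn differed by 0.23 between the guides (SE 0.0775, edgeR adjusted p = 0.549). Replicates 3 and 4 alone, chosen after seeing the data, called 10 genes, among them Rhox5, Cdh2 and Cdkn1c.

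Of the genes called with each guide, 2110 were called with both in the same direction, 1291 higher and 819 lower, and 0 in opposite directions. Independent lists of these sizes would share 216 higher and 125 lower genes. The fold changes of the guides correlated across 14497 genes with a Pearson r of 0.937 and a covariance of 0.255, where genes are not independent replicates. In 20 simulations of unchanged groups against shared NT libraries, at most 1 gene was shared, the mean r was 0.508 and the mean covariance 0.017, a difference in covariance of 0.238. These simulations left out that same-numbered guide libraries deviated together (correlations from 0.21 to 0.5), so any part of the shared count, r or covariance from that is not in the simulated values. With the NT libraries split between the guides in 6 ways, 794 to 1015 genes were shared, with r from 0.755 to 0.866 and covariance from 0.239 to 0.254. In 1 of these splits, with Mycn-gRNA2 set against NT replicates 1 and 2, 4 genes were called in opposite directions, and in the other 5 splits 0. A difference that all NT libraries share, such as the near absence of Y-linked transcripts, stays in every split. The shared calls therefore do not separate such a difference from an effect of the guides. The shared count was 3735 without Mycn-gRNA2 replicate 1 and 32 with replicates 1 and 2 alone.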

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

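The tests of the 3 patterns below were chosen after the results they bear on had been seen, except the regression on GC content and gene length, which was set beforehand together with the counts of other splits of the libraries. The Y-chromosome tests were also changed after a first run, which changed their outcomes for depth, loss of the Y chromosome and shared reads. That run included the pseudoautosomal gene Erdr1 among 6 Y genes and used 6 X-linked copies, among them Usp9x and Zfx, whose Y partners were not tested. In it depth was not excluded (lowest guide library 89.5 CPM, highest NT library 41.1 CPM), loss of the Y chromosome was excluded (highest NT level 43% of the guide level), and shared reads were favoured (gain of the X-linked copies 194 CPM, SE 59). Erdr1, Usp9x and Zfx were then left out, Uba1 was added, and genes under 1 CPM in the guide libraries were no longer allowed to exclude loss of the Y chromosome, a limit set when the level of Uba1y was known. The test of MYC targets in Mycn-gRNA2 replicate 2 was made stricter after its values were seen.

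Y-linked transcripts were near 0 in all 4 NT libraries and present in all 8 libraries with a Mycn guide. The summed level of 5 male-specific Y genes was 0.486 ± 0.297 CPM in NT (SD, n = 4), 60.6 ± 21.3 CPM with Mycn-gRNA2 (SD, n = 4) and 58.3 ± 7.91 CPM with Mycn-gRNA3 (SD, n = 4). Lower depth in NT is excluded, since the lowest guide library stood at 33.1 CPM and the highest NT library at 0.857 CPM. A candidate explanation is an NT culture without a Y chromosome, and the test left it open, because Uba1y kept 41.7% of its guide level, though at only 0.88 CPM in the guide libraries, while the other 4 genes kept under 0.4%. Reads assigned to X-linked copies could also matter, but their gain in NT of 72.7 CPM (SE 51.5) decides nothing, and a response to the guides, with NT at 0.818% of the guide mean, cannot be told apart from a difference between cultures, because every NT library shares it.

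Genes of chromosomes 1 and 8 were lower with both guides, with median log2 fold changes of −0.13 and −0.12 over genes with a mean log2 CPM above 3. GC content and gene length as the whole cause are excluded, since after regression on them the less shifted of the pair still stood at −0.086, against −0.027 for the lowest other chromosome, and a few genes as the cause are excluded too, since 100% of the 16 stretches of 20 Mb on these chromosomes had a median below 0, as did 100% of the 5 on chromosome 14 (median −0.07) and the 5 on chromosome 18 (median −0.03), so this is not particular to chromosomes 1 and 8. By library, Mycn-gRNA2 replicate 2 stood at −0.00377 for chromosome 1, inside the NT range of −0.0253 to 0.0189, and at −0.0826 for chromosome 8, close to the other guide libraries, which ran from −0.184 to −0.0996 for chromosome 1 and from −0.144 to −0.0874 for chromosome 8. Both medians lay below the lowest chromosome median after shuffling genes between chromosomes (permutation p = 1e-04, the smallest that 10000 draws can give). The shuffle treats genes as independent, so its p does not measure variation between libraries or cultures. It also cannot tell which cause moved a chromosome. Extra copies of both chromosomes in part of the NT cells may account for the shift. The labels give no karyotype, so extra copies stay a hypothesis, and with them the possibility that the NT cells differ from the guide cells by more than the guide.

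Mycn-gRNA2 replicate 2 lay between NT and the other Mycn-gRNA2 libraries, with a first principal component of 3.07 against 12.5 to 18.5 for the other 3. A wrong label is excluded, since the 19 genes near 0 in NT stood at a median of 0.493 of the distance from NT to the other Mycn-gRNA2 libraries (interval 0.394 to 0.58). A mix with NT-like cells could account for those genes, whose quartiles of 0.391 and 0.59 lie close together, and the 7 called fibroblast genes (median 0.641, interval 0.484 to 0.697) and 3 glycolysis and hypoxia genes (0.701, 0.555 to 0.755) also lay between the groups, while the interval of the 11 primitive endoderm genes (0.778, 0.584 to 1.13) reached the other Mycn-gRNA2 libraries. The 18 MYC target genes called higher with Mycn-gRNA2 without that library stood at a median of 1.08 (interval 0.882 to 1.35). Their ratio to the near-0 genes was 2.19, against 0.441 to 1.41 in the other guide libraries, where their own median ran from 0.499 to 1.5. For these genes the ratio argues against a mix as the only cause but does not exclude it. The interval resamples genes that move together (estimated correlation over the list 0.398), and 1.08 lies inside the range of the other guide libraries. No biological explanation was tested, because the design names none for a single library.

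In 381 groups of 4 libraries, 21 held a value far from the other 3, where chance alone, at about 1 in 20 groups, gives about 19. Among NT libraries, replicate 1 had the isolated values for Kdm5d (0.0451 CPM), Rcan2 (8.98 CPM) and Dlx3 (0.496 CPM), replicate 2 for Ung (69.6 CPM), and replicate 3 for Eif2s3y (0 CPM), Nop58 (722 CPM), Rpl41 (470 CPM) and Col3a1 (0.0396 CPM). Kdm5d (1 read against 0 in the other NT libraries) and Eif2s3y (0 reads against 1) are at the floor. So is Col3a1, at 0 CPM in the other NT libraries, and these values do not set a library apart. Among Mycn-gRNA2 libraries, replicate 1 stood apart for Fgf17 (36.8 CPM), Ung (64.3 CPM), Aurka (161 CPM) and Hist1h2bc (8.73 CPM), replicate 2 for Polr2a (657 CPM), replicate 3 for Aldh18a1 (59.6 CPM) and replicate 4 for Myc (137 CPM). Among Mycn-gRNA3 libraries, replicate 1 stood apart for Ccne1 (94.5 CPM) and Hmgb2 (953 CPM), and replicate 3 for Rpl36 (363 CPM), Nupr1 (1.77 CPM), Cox8a (119 CPM) and Tap1 (4.56 CPM). The test of the difference between the guides per cell singled out Rhox5, at 1.02 on the log2 scale (edgeR adjusted p = 0.0114).

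Other splits of the same libraries rarely called as many genes as the real groups. For both guides against NT, 1 of 100 sampled splits, the real one, reached the relative count of 4034 (highest other 2046). The per-cell count of 8312 was also reached by 1 of 100 (highest other 7894). A chance sorting of single libraries can thus be excluded for these. The same holds for Mycn-gRNA2 relative to the transcriptome (1 of 35 splits, real 2485, highest other 12) and for Mycn-gRNA3 on both scales (1 of 35 splits each, real 3919 and 8867, highest other 0). The splits cannot exclude a difference between cultures that all NT libraries share, since the labels do not say whether replicates are separate cultures. For Mycn-gRNA2 per cell chance cannot be excluded, since 2 of 35 splits reached its 3892 genes, and exchanging NT replicate 2 with Mycn-gRNA2 replicate 2 gave 8565. Between the guides all 35 splits reached the real count of 0, and the highest, 308, parted replicates 1 and 2 of both guides from replicates 3 and 4, which points to a structure of the samples along the replicate numbers. With the number as a block the count stayed at 0.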

How the results depend on the processing

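Settings that part or drop replicates jointly, the term for replicates 1 and 2 against 3 and 4, and the tests without chromosomes 1, 8, X and Y were chosen after seeing the data. No result reversed, and Mycn kept its direction under each setting and its call under all but replicates 1 and 2 alone. Of 2440 values for 122 named genes, 2291 stayed on their side of the threshold and 149 lost the call, 92 of them with replicates 1 and 2 alone, and 16 genes lost it without some single library, most often Mnt (8 libraries, adjusted p up to 0.128) and Cox7c (7 libraries, up to 0.129).

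With only the compared groups in the fit, relative counts were 1549 for Mycn-gRNA2 and 6040 for Mycn-gRNA3, each with its own spread estimate. A 1.5-fold minimum gave 1471, 1163 and 1590 (both guides, Mycn-gRNA2, Mycn-gRNA3) relative to the transcriptome and 3570, 2233 and 5171 per cell, by construction. DESeq2 called 1 gene between the guides. DESeq2, other size factors and no filter left every other count within 1.5 times, and DESeq2 shared 3922 of 4034 calls for both guides. Limma on the deposited log2 values called 7448, 2788 and 8256 genes per cell. For gene lists, an estimated correlation gave 0, 0 and 0 calls, and fry, which does not compare a list with other genes, gave 14 for both guides.

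Replicates 1 and 2 alone gave 178, 33 and 226 relative and 1113, 410 and 2792 per-cell calls, 32 shared genes, 5 lists for both guides and 4 for Mycn-gRNA3, and for Mycn with Mycn-gRNA2 0.58 (adjusted p = 0.0918) and per cell 0.70 (adjusted p = 0.13). Replicates 3 and 4 alone gave 6385, 4830, 5955 and, between the guides, 10 relative calls, 8200 per cell for Mycn-gRNA2 and 4398 shared genes. The cause of the gap between the pairs was not tested. Endogenous RNA per ERCC read moved by 0.32 (exact permutation p = 0.267) and 0.46 (exact permutation p = 0.0667) for both guides in these subsets and by 0.46 and 0.46 for Mycn-gRNA3 (exact permutation p = 0.333 each), where few libraries limit p. Without Mycn-gRNA2 replicates 1 and 2 relative counts were 6603, 4412 and 6318, Mycn-gRNA2 per cell 9023 and shared genes 3995, and the cause was not tested. Leaving out genes of chromosomes 1, 8, X and Y gave 3348, 2075 and 3262, within 1.5 times.

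With each library left out, relative counts ranged from 2929 to 6157 for both guides, 1619 to 4114 for Mycn-gRNA2 and 2654 to 6012 for Mycn-gRNA3, the highest each time without Mycn-gRNA2 replicate 1. Per cell the ranges were 5599 to 10275, 1866 to 7946 and 6838 to 9978. Shared genes ran from 1453 to 3735, called lists from 6 to 10, 5 to 11 and 8 to 11, and endogenous RNA per ERCC read from 0.36 to 0.44, 0.23 to 0.42 and 0.43 to 0.51. The cause was not tested. Lists gained calls too: oxidative phosphorylation (3 libraries), histones (3), translation factors (2) and ribosomal proteins (1) for both guides. Others were formative and primed epiblast (2), oxidative phosphorylation (1) and translation factors (1) for Mycn-gRNA2, and translation factors (1) for Mycn-gRNA3.

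For NT and the guides, same-numbered libraries had correlations of deviations from 0.033 to 0.37, and libraries did not all correlate best with their own number. The main fits therefore did not pair NT with the guides. The numbers do tie NT to the guides in part, since the second principal component parted replicates 1 and 2 from 3 and 4 in NT as well. With the number as a block, relative counts were 4456, 2807 and 4414 and per-cell counts 7525, 3208 and 8283, and the RNA difference of 0.39 for both guides and 0.46 for Mycn-gRNA3 had an exact sign-flip p of 0.125, the smallest that 4 pairs allow. With the block camera called 10 lists for both guides in place of 9, and otherwise the block changed no call of a named gene and moved no count of genes by over 1.5 times. Depth limits genes of a few reads: the largest rises were given as read ratios, and fitted changes of other low genes, such as Wnt3 at 0.194 CPM in NT, depend on the prior count.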

Other observations

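The list tests in this part were planned, and the principal components of replicates 1 and 2 against 3 and 4 were looked at without a plan.

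Imprinted genes moved both ways with both guides against NT. Of 33 tested, 12 rose and 7 fell relative to the transcriptome (12 and 7 adjusted over the list alone, camera adjusted p = 0.21). H19, a maternally expressed RNA, rose by 1.89 on the log2 scale from 2.46 ± 0.645 CPM (SD, n = 4), Peg12 by 1.44 and Slc38a4, an amino acid transporter expressed from the paternal copy, by 0.57, while the maternally expressed Rian fell by 1.08 and also fell per cell, by 0.71. Of 22 interferon response genes, 6 rose and 4 fell relative to the transcriptome (7 and 4 adjusted over the list alone, camera adjusted p = 0.515): Tap1, a peptide transporter, rose by 1.15 and Ifitm3 by 0.39, while Irf9 fell by 0.34, Xaf1 by 0.77 and Ddx58 by 0.44, and of these Xaf1 alone fell per cell. Of 27 p53 targets and CDK inhibitors, Dcxr rose by 1.09, Cdkn1a, a CDK inhibitor, by 0.73, Zmat3 by 0.35 and Ddit4l by 1.16, while Ddb2 and Rrm2b fell relative to the transcriptome but not per cell (4 and 2 adjusted over the list alone, camera adjusted p = 0.381).

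Of 43 lysosome and autophagy genes, 5 rose and 8 fell relative to the transcriptome, and 0 fell per cell (6 and 8 adjusted over the list alone, camera adjusted p = 0.785). Rragd, a GTPase that links amino acids to mTOR, rose by 0.77 and Ctsz, a cathepsin, by 0.43, while Atp6v1b2, a subunit of the proton pump, fell by 0.32 relative to the transcriptome. Of 13 trophoblast genes, Krt8 rose by 0.56 and Dlx3 by 0.73, and Tfap2a fell by 0.84 (2 and 1 adjusted over the list alone, camera adjusted p = 0.515). The Dlx3 call ended without NT replicates 2, 3 or 4 or Mycn-gRNA3 replicate 4 (edgeR adjusted p from 0.0501 to 0.0736). Of 2 tested 2-cell-like genes, Sp110 fell by 0.75 relative to the transcriptome but not per cell (0 and 1 adjusted over the list alone, camera adjusted p = 0.383), a call that ended without NT replicates 1, 2 or 3, Mycn-gRNA2 replicate 3 or Mycn-gRNA3 replicates 3 or 4 (edgeR adjusted p from 0.0588 to 0.0947). Of 31 genes on the histone list, Hist1h2bc rose by 0.47 and H1f0, a linker histone made outside S phase, fell by 0.27 relative to the transcriptome but not per cell (0 and 0 adjusted over the list alone, camera adjusted p = 0.101). The Hist1h2bc call ended without NT replicates 2, 3 or 4 or Mycn-gRNA3 replicates 3 or 4 (edgeR adjusted p from 0.0528 to 0.102), and the H1f0 call without NT replicate 2 (0.0546). None of the 15 mitochondrially encoded genes on the list matched a name in the count table.

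The first principal component of the 1000 most variable genes held 65.9% of the variance and parted NT from the guides. The second held 11.4% and was positive in replicates 1 and 2 and negative in replicates 3 and 4 of all 3 groups. The labels name no batch.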
